A study of Mus musculus with 28 samples.

How the data were processed

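Hypothalami were taken from mice that carry the LepRb-eGFP-L10a reporter, in which the ribosomal protein L10a fused to eGFP is made in cells that express the long leptin receptor isoform, LepRb. Per the labels' protocols, male and female mice of 10 to 13 weeks were fasted from lights-on. They received metreleptin (5 mg per kg, intraperitoneal) or vehicle, and tissue was taken 3 or 10 h later. The protocol names 0.9% saline as the vehicle and the treatment labels name PBS; the samples are called vehicle here. Antibodies against eGFP pulled down the tagged ribosomes with their RNA (bead fraction), and the liquid that remained was kept as the depleted fraction. The 28 libraries came from 14 lysates, each with 1 bead and 1 depleted library. In each fraction there were 4 vehicle and 3 leptin lysates of wild-type mice at 3 h, 1 vehicle and 3 leptin lysates of wild-type mice at 10 h, and 2 vehicle and 1 leptin lysate of ob/ob mice, which lack functional leptin, at 10 h. Whether a lysate held tissue of 1 mouse or of several is not given in the sources used here.

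Per the labels' protocols, RNA with an integrity number of at least 8 was made into poly(A)-selected libraries with a kit that does not mark the strand, and sequenced 4 libraries per lane as single-end reads of 50 cycles. Per the submitters' processing notes, STAR 2.7.6a and the mouse genome build GRCm38.p6 were used. The table the authors deposited holds raw counts of reads per gene with no normalization, as whole numbers for 55487 genes and 28 libraries. The counting program, its strand setting and the annotation release are not given in the sources used here. A further deposited file lists the sequencing run of each library: 1 run held all 14 wild-type libraries of 3 h, another the 8 wild-type libraries of 10 h and the last the 6 ob/ob libraries. Time, genotype and run therefore cannot be told apart, while leptin and vehicle were compared within each run.

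Total counts ranged from 21277982 to 42267040 per library in beads and from 19649105 to 41804049 in the depleted fraction. The 10 largest genes together took 2.65% to 4.24% of a library. Molecular identifiers are not described in the sources used here, so the depth bounds the counting error only. Gene positions were taken from a GRCm38 annotation, in which 55141 of the 55487 IDs of the table were found; 234 genes share a symbol with another and were kept by ID.

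Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with at least 10 counts in at least 3 libraries of a fit were kept, libraries were scaled by TMM, and the quasi-likelihood F test with the robust option was used, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values in the report come from this test unless another tool is named. They measure an effect against the spread between samples, which groups of 1 library borrow from the other groups. Camera p-values instead compare a list with the other genes, and Fisher's exact test compares counts of genes. With no true difference, 911 of 18212, 956 of 19115 and 984 of 19682 genes tested would be expected at an unadjusted p under 0.05. Bead and depleted libraries were compared over all 14 lysates with the lysate as a block, because both come from the same tissue. As a check of that pairing, the deviations of the bead and depleted library of a lysate from their group means were correlated; r was 0.0812 to 0.33, and each of the 10 lysates that could be checked correlated best with its own partner. Leptin effects within a fraction came from 1 fit of the 14 libraries of that fraction with a coefficient for each of 6 groups, so that groups of 1 library borrow the spread of the others, with 8 residual degrees of freedom. The effect at 10 h was the mean of the wild-type and the ob/ob effect. A response shared by all times and genotypes was fitted with a term for stratum (wild type 3 h, wild type 10 h, ob/ob 10 h) and a term for leptin. Differences of the leptin effect between fractions, between 10 h and 3 h and between ob/ob and wild type were tested as contrasts of these models. Levels are CPM (counts divided by the library total and multiplied by 1e6) scaled by TMM, given as mean ± SD.

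A total of 23 gene lists, 11 of pathways or neuron types and 12 of other cell types, were written before the data were examined, with 332 of their 333 genes in the table: markers of LepRb neurons, feeding neuropeptides, JAK-STAT feedback, immediate early genes, ER stress and integrated stress response, interferon response, acute phase and serpin genes, secretory processing, circadian clock, glucocorticoid and fasting response, synaptic receptors, and markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, ependymal cells and tanycytes, choroid plexus, erythrocytes, pituitary, neurons in general, hypothalamic neurons without LepRb, and sex-linked genes. Several members, among them the Serpina3 genes, Timp1 and Asb4, were put on these lists from knowledge of leptin-regulated hypothalamic genes, which may rest in part on earlier work with this reporter. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 23 lists of a comparison. Members past the threshold were counted over all genes and with adjustment over the list alone. A list of 20 striatal genes, a list of nuclear RNAs and the genes near Lep were written after the data had been seen.

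The genes named per comparison followed a rule set before the data were examined: Lepr, Atf3, Socs3, Agrp, Npy, Pomc and Cartpt always; up to 10 genes with the largest and 10 with the smallest log2 fold change among genes past the threshold with a mean of at least 1 CPM and no overlap between the libraries compared (the same sign in all 14 lysates for the enrichment); and up to 4 passing members per list, or up to 2 members as values where none passed. The choice of main model, tests, filter, gene lists and most alternatives was also made before the data were examined. Alternatives were RLE size factors, library totals, DESeq2 1.42.0, limma voom, no filter on counts, a filter of 1 CPM in 7 libraries, no robust option, no lysate block, parts of the libraries alone, a glial index (the mean log2 CPM of 36 astrocyte, oligodendrocyte and microglia markers) or the letter m or f of the titles as a covariate, a minimum fold of 2, and each lysate left out in turn. Fits without the lysates richest in pituitary transcripts, and the use of the 50 genes with the smallest p at 3 h, were added after the data had been seen. So were the ob/ob effect alone in the depleted fraction at 10 h and the genotype difference in leptin or vehicle libraries alone. Calls were also counted under up to 100 other splits of the same libraries.

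The code was tested on simulated data with 200 genes changed in counts drawn from the real means and library sizes. For the bead comparison at 3 h, 32.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold were called; for the wild-type bead comparison at 10 h the shares were 4.48%, 32.8% and 89.4%, and for the ob/ob comparison at 10 h 0%, 34.3% and 84.8%. Mouse phenotypes and other assays of the study were not analysed here.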

Results

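Gene expression was measured by RNA-seq of RNA bound to eGFP-tagged ribosomes of LepRb cells (bead fraction) and of the RNA left after their removal (depleted fraction) in the hypothalamus of leptin- and vehicle-treated mice. In each fraction there were 4 vehicle and 3 leptin libraries of wild-type mice at 3 h, 1 vehicle and 3 leptin libraries of wild-type mice at 10 h, and 2 vehicle and 1 leptin library of ob/ob mice at 10 h. Total counts were 21277982 to 42267040 per bead library and 19649105 to 41804049 per depleted library. The 3 h libraries carry the letters m and f in their titles, and the letter was balanced between the arms to within 1 lysate. Library kits did not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart.

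The comparison of bead with depleted RNA asked which transcripts are enriched on tagged ribosomes of LepRb cells. It also sets RNA bound to ribosomes against RNA that includes unbound transcripts. Differences in ribosome binding and in cell type therefore cannot be told apart in it. The receptor itself, Lepr (ENSMUSG00000057722; GRCm38 chromosome 4, 101717404 to 101815352), was 4.86-fold higher in beads (log2 fold change 2.28, SE 0.0948, n = 14 lysates, adjusted p = 8.28e-14) and higher in all 14 lysates. Agrp, which codes for the appetite-stimulating agouti-related peptide (ENSMUSG00000005705; chromosome 8, 105566698 to 105637393), was 39.2-fold higher (log2 5.29, SE 0.138). Npy, its companion orexigenic peptide (ENSMUSG00000029819; chromosome 6, 49822710 to 49829507), was 26.9-fold higher (log2 4.75, SE 0.179). Pomc, the precursor of the anorexigenic peptide alpha-MSH (ENSMUSG00000020660; chromosome 12, 3954951 to 3960642), was 20.8-fold higher (log2 4.38, SE 0.46). All 3 were higher in all 14 lysates. Prlh, which codes for prolactin-releasing hormone, was 33-fold higher, Cartpt 8.97-fold, Ghrh 9.89-fold, and Gsx1, a homeobox gene of arcuate neuron development, 11.8-fold. Cited1, Krt90, Tbx19 and Serpina3i were also among the 10 genes with the largest rise of those with at least 1 CPM and the same sign in all 14 lysates, with log2 fold changes of 3.20, 3.46, 3.30 and 3.61. Timp1, a metalloproteinase inhibitor, rose 15-fold and Atf3, a transcription factor of the stress response, 7.53-fold. Lysates of leptin-treated mice are part of this comparison. For genes that leptin raised in beads, such as Timp1 and Atf3, the enrichment can therefore restate part of the leptin effect. In the annotation the Agrp gene model overlaps several other genes, including Ctcf on the other strand, and the Serpina3 genes are near-identical paralogs, so the values of these genes are uncertain where reads could be split or shared.

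Of the lists of neuron types and pathways, 22 of 24 measured LepRb neuron markers rose in beads, 1 fell and 1 did not pass (median log2 fold change 2.36, camera adjusted p = 3.68e-10; adjusted p = 0.21 with an estimated correlation). Nr5a1, a transcription factor of the ventromedial nucleus, rose by 2.76 on the log2 scale and Calcr, the calcitonin receptor gene, by 2.16. Of 23 feeding neuropeptides 17 rose, 5 fell and 1 did not pass (median 1.61, adjusted p = 0.0027; adjusted p = 0.156 with an estimated correlation), among them Gal (1.97), Crh (1.96) and Adcyap1 (1.84). Secretory processing genes rose in 14 of 16 cases and 1 fell (median 0.65, adjusted p = 3.83e-05; adjusted p = 0.156 with an estimated correlation), with Scg2 at 1.30 and the prohormone convertase gene Pcsk1 at 1.20. Of 25 genes of ER stress 21 rose and 2 fell (median 0.48, adjusted p = 1.24e-05; adjusted p = 0.308 with an estimated correlation), including the chaperone gene Hspa5 (1.01) and Xbp1 (0.90). Of 15 glucocorticoid and fasting genes 3 rose and 12 fell (median -0.73, adjusted p = 0.011; adjusted p = 0.278 with an estimated correlation), with Sgk1 at -0.98.

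Markers of astrocytes, oligodendrocytes, microglia, ependymal cells and erythrocytes were lower in beads. All 12 astrocyte markers fell (median -1.16, adjusted p = 7.66e-05; adjusted p = 0.36 with an estimated correlation). So did all 12 oligodendrocyte markers (median -1.59, adjusted p = 4.05e-06; adjusted p = 0.308 with an estimated correlation) and all 12 microglia markers (median -1.68, adjusted p = 3.93e-05; adjusted p = 0.308 with an estimated correlation). Sox9 of astrocytes stood at -1.42, Cnp of oligodendrocytes at -1.29 and the complement gene C1qb of microglia at -1.79. Ependymal and tanycyte markers fell in 11 of 12 cases (median -0.84, adjusted p = 0.00339; adjusted p = 0.308 with an estimated correlation) and erythrocyte genes in 5 of 5 (median -1.62, adjusted p = 0.0035; adjusted p = 0.278 with an estimated correlation). The remaining lists did not pass as sets: oligodendrocyte precursors (1 of 6 rose, 5 fell, adjusted p = 0.0756) and choroid plexus (1 of 7 rose, 6 fell, adjusted p = 0.0678). The same held for pituitary markers (6 of 6 fell, adjusted p = 0.0756), endothelial and mural cells (5 of 12 rose, 2 fell, adjusted p = 0.601) and the acute phase list (8 of 15 rose, 3 fell, adjusted p = 0.127). JAK-STAT feedback genes (11 of 22 rose, 5 fell, adjusted p = 0.137) and interferon genes (13 of 26 rose, 7 fell, adjusted p = 0.421) did not pass. Synaptic receptors (12 of 21 rose, 7 fell, adjusted p = 0.21) and clock genes (5 of 19 rose, 9 fell, adjusted p = 0.21) did not pass either. General neuronal genes (7 of 12 rose, 4 fell, adjusted p = 0.413) and hypothalamic neurons without LepRb (4 of 10 rose, 5 fell, adjusted p = 0.455) went both ways. Immediate early genes (11 of 25 rose, 7 fell, median -0.08, mean 0.10, adjusted p = 0.865) and sex-linked genes (2 of 5 rose, 2 fell, median -0.18, mean 0.12, adjusted p = 0.639) had a median and a mean of opposite sign.

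**Figure D1:**
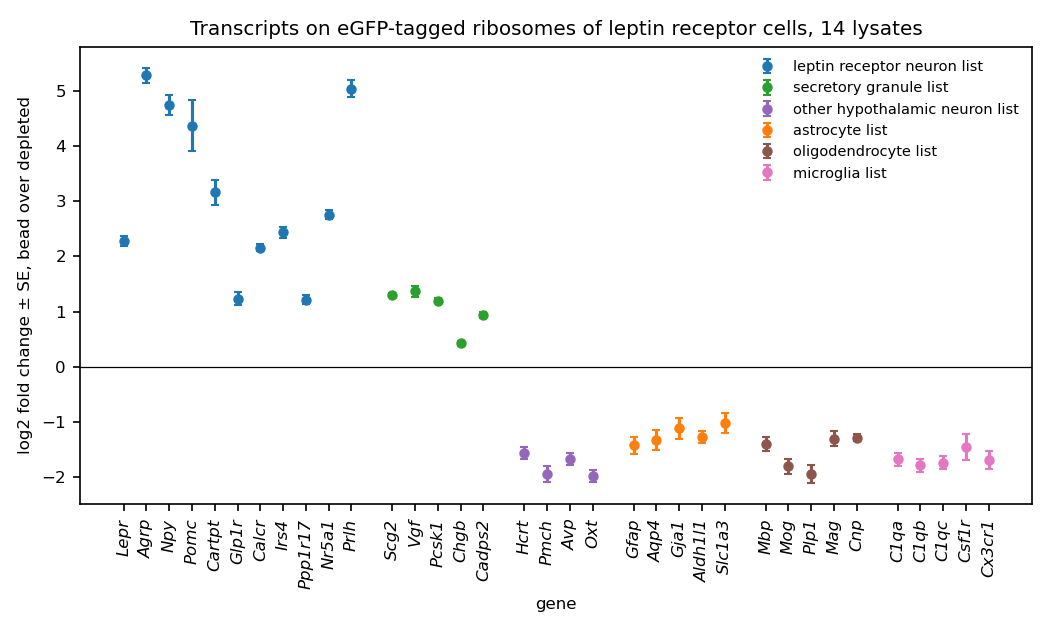
Log2 fold change of bead over depleted RNA (points, with SE as bars, 14 lysates) for marker genes of 6 lists, one colour per list; the horizontal line marks no difference. Agrp at 5.29 and Lepr at 2.28 lie above it and the microglia gene C1qb at -1.79 below it.

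In all, 15333 of 19682 genes tested differed between the fractions (edgeR quasi-likelihood test with lysate block and Benjamini-Hochberg adjustment), 7603 higher and 7730 lower in beads, of which 745 and 2728 differed at least 2-fold. The values are relative to the mean of the library, and the split depends on the scaling: with library totals alone 5393 were higher and 9925 lower, with the median of all genes shifted by -0.178. Transcripts encoded in mitochondria were among the lowest, with mt-Cytb at -4.82 and mt-Nd2 at -4.78, and the short non-coding RNA Bc1 stood at -5.32.

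The comparison of leptin with vehicle 3 h after injection asked which transcripts change early in LepRb cells. The transcripts of 4 genes rose in beads and none fell. Arid5a, which codes for an RNA-binding protein that stabilises cytokine-response transcripts (ENSMUSG00000037447; chromosome 1, 36307733 to 36324029), rose 4.16-fold, from 9.38 ± 1.21 CPM (SD, n = 4) to 39.3 ± 14.1 CPM (n = 3; log2 2.06, SE 0.2, adjusted p = 0.000773). Etv6, an ETS-family transcriptional repressor (ENSMUSG00000030199; chromosome 6, 134035700 to 134270158), rose 2.65-fold, from 14.6 ± 1.3 to 38.9 ± 8.96 CPM (log2 1.41, SE 0.151, adjusted p = 0.00136). Socs3, the feedback inhibitor of leptin receptor signalling (ENSMUSG00000053113; chromosome 11, 117966079 to 117970047), rose 4.42-fold, from 9.89 ± 1.03 to 43.9 ± 16.7 CPM (log2 2.14, SE 0.249, adjusted p = 0.00355). Atf3 (ENSMUSG00000026628; chromosome 1, 191170296 to 191218039) rose 4.81-fold, from 6.39 ± 1.53 to 30.9 ± 13.3 CPM (log2 2.27, SE 0.326, adjusted p = 0.0453). For each of the 4 genes every leptin library lay above every vehicle library. Small or antisense genes overlap Atf3 and Etv6 in the annotation.

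Lepr (-0.08, adjusted p = 0.939), Pomc (-0.17, adjusted p = 0.844), Cartpt (-0.14, adjusted p = 0.929), Npy (-0.38, adjusted p = 0.844) and Agrp (-0.54, adjusted p = 0.812) did not pass at 3 h. Of 22 JAK-STAT feedback genes 1 rose over all genes and 7 rose adjusted over the list alone (Socs3, Cish, Socs2, Stat3, Jak2, Ptpn1 and Ptpn2; camera adjusted p = 4.75e-07, adjusted p = 0.0548 with an estimated correlation). Of 25 immediate early genes none passed over all genes and 3 rose adjusted over the list alone, with Jun at 0.89 (adjusted p = 0.136 over all genes; list adjusted p = 0.0202, adjusted p = 0.531 with an estimated correlation). Of 19 clock genes 3 rose adjusted over the list alone, with Bhlhe40 at 0.55 (adjusted p = 0.106 over all genes; list adjusted p = 0.111). Of 23 feeding neuropeptides 2 fell adjusted over the list alone, Pnoc and Trh (list median -0.34, adjusted p = 7.73e-07; adjusted p = 0.084 with an estimated correlation). Markers of glia had lower values in the same libraries, with medians of -0.60 for astrocytes (adjusted p = 0.00071), -0.31 for oligodendrocytes (adjusted p = 0.0106) and -0.57 for microglia (adjusted p = 0.000406), no member past the threshold. These lists had adjusted p = 0.483, 0.483 and 0.468 with an estimated correlation. The mean log2 CPM of 36 glial markers was 4.56 in vehicle and 4.16 in leptin beads. Endothelial and mural markers (median -0.80, 12 of 12 negative, adjusted p = 0.000406) and ependymal and tanycyte markers (median -0.49, 12 of 12 negative, adjusted p = 0.000406) were lower by the same test, each with adjusted p = 0.468 with an estimated correlation. In all 15 of 23 lists passed at the preset correlation and 0 with an estimated one.

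**Figure D2:**
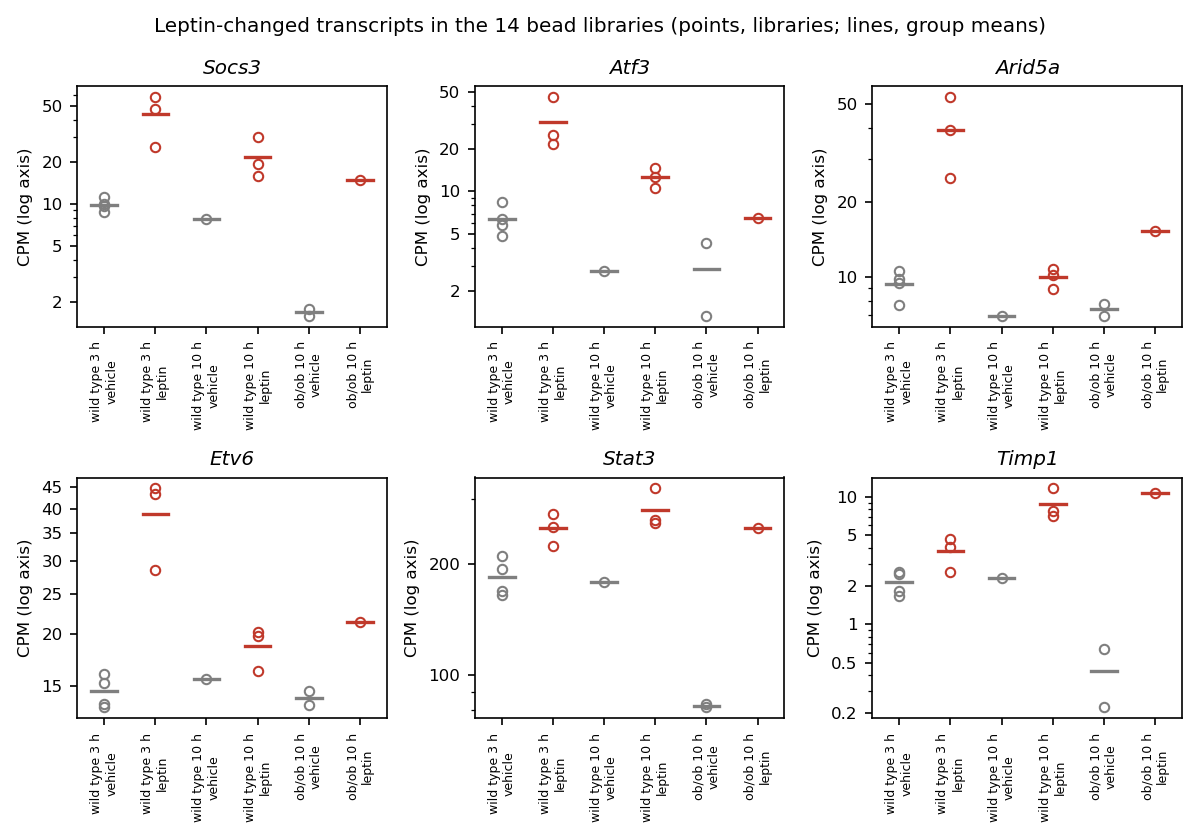
CPM on a log axis of 6 genes in the 14 bead libraries, by group (points are libraries, lines are group means; grey vehicle, red leptin). Socs3 means were 9.89 and 43.9 CPM in wild-type vehicle and leptin beads at 3 h, and Timp1 stood at 0.43 CPM on average in ob/ob vehicle beads and at 10.8 CPM in the ob/ob leptin library at 10 h.

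At 3 h in beads 4 of 18212 genes passed and 1363 had an unadjusted p under 0.05; DESeq2 called 22 and limma voom 4. With the glial index as a covariate Socs3 (1.96, adjusted p = 0.0906) and Atf3 (2.38, adjusted p = 0.182) lost their calls. Library totals also took the call from Atf3 (2.26, adjusted p = 0.0652). Atf3 lost its call when any of 6 of the 7 lysates was left out (all except leptin f2), with adjusted p from 0.0722 without leptin m24 to 0.24 without vehicle f1 and log2 fold changes of 1.89 to 2.43. Vehicle lysate m3 and leptin lysate f2 carried far more pituitary hormone transcripts than the other 3 h lysates (Gh 233 and 1270 CPM in the depleted fraction against at most 1.40 CPM). Without these lysates 34 genes passed, 30 higher and 4 lower, the original 4 among them. These 2 lysates were also the ones whose glial means made the arms overlap (3.94 in vehicle m3, 4.61 in leptin f2); without them the means were 3.81 and 4.07 in leptin against 4.44 to 5.19 in vehicle beads, so this fit does not separate leptin from glial content. Genes added in that fit, which was chosen after the data had been seen, included Gadd45a (log2 1.35), Serpina3i (1.64), Socs2 (1.03), Jun (1.04) and Cish (1.11).

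In the depleted fraction the same comparison asked whether the response was seen in the RNA left after the pull-down. That RNA can still hold transcripts of LepRb cells, so it does not measure other cells alone. None of 19115 genes passed by edgeR, which gave 1813 genes with an unadjusted p under 0.05; DESeq2 called 62 and limma voom 0. Socs3 stood at 0.97 (SE 0.174, adjusted p = 0.2) and Atf3 at 0.68 (SE 0.192, adjusted p = 0.374). Of 12 microglia markers 11 fell adjusted over the list alone (median -0.59, list adjusted p = 5.95e-15; adjusted p = 0.227 with an estimated correlation), with C1qc at -0.61 and the protease gene Ctss at -0.82. Of 23 feeding neuropeptides 11 fell adjusted over the list alone (median -0.35, list adjusted p = 7.79e-15; adjusted p = 0.227 with an estimated correlation), with Pnoc at -0.41 and Sst, the somatostatin gene, at -0.41. Pomc stood at 2.10 (SE 1.03, adjusted p = 0.573) and at -0.26 (SE 0.252) without the 2 lysates rich in pituitary transcripts. In all 14 of 23 lists passed at the preset correlation and 0 with an estimated one.

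The leptin effect at 3 h was larger in beads than in the depleted fraction for 2 of 19682 genes, Arid5a (difference of log2 fold changes 1.84, SE 0.222, adjusted p = 0.00742) and Etv6 (1.14, SE 0.145, adjusted p = 0.00783). Arid5a did not pass as enriched in beads over the 14 lysates (-0.28, SE 0.219, adjusted p = 0.247); its level in vehicle mice at 3 h was 9.38 ± 1.21 CPM in beads and 15.7 ± 0.763 CPM in the depleted fraction (n = 4). Socs3 (1.11, adjusted p = 0.35) and Atf3 (1.54, adjusted p = 0.35) did not pass this test. Of 22 JAK-STAT feedback genes 5 passed adjusted over the list alone (list adjusted p = 3.33e-06; adjusted p = 0.0521 with an estimated correlation). The edgeR test gave 619 genes with an unadjusted p under 0.05 (984 expected with no true difference), DESeq2 called 7 and limma voom 2. Arid5a lost its call without leptin m24 (adjusted p = 0.127), and Etv6 without leptin m24 (adjusted p = 0.138), leptin f4 (adjusted p = 0.148) or vehicle m1 (adjusted p = 0.0689). Without the 2 lysates rich in pituitary transcripts 79 genes passed, 31 higher and 48 lower, and the arms did not overlap in glial content (3.81 and 4.07 against 4.44 to 5.19). Of the 48 lower genes 46 had lower estimates in beads than in the depleted fraction.

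**Figure D3:**
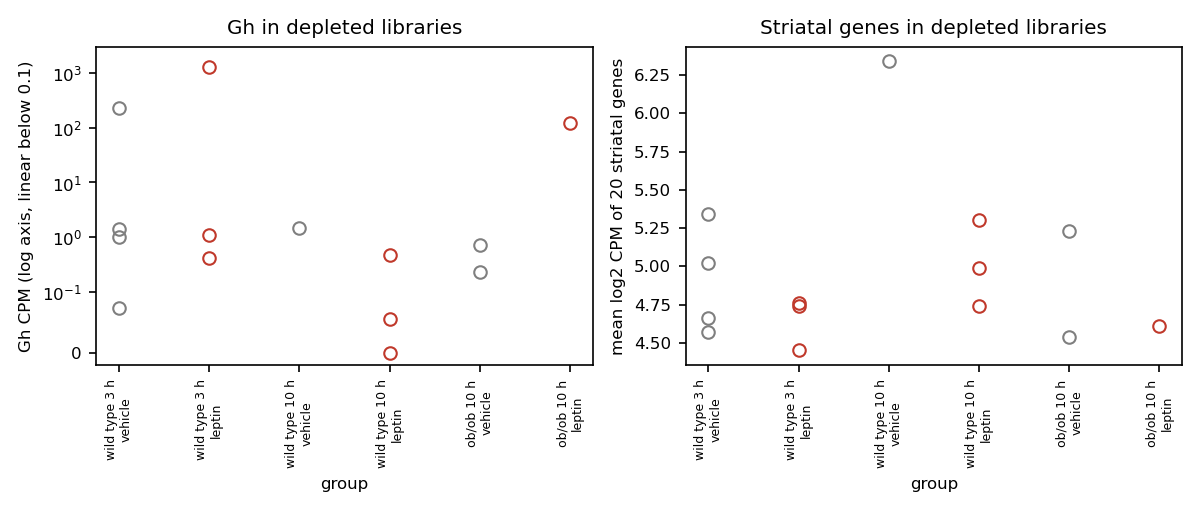
Transcripts of neighbouring tissues in the 14 depleted libraries by group (points are libraries; grey vehicle, red leptin): Gh in CPM on a log axis that is linear below 0.1, and the mean log2 CPM of 20 striatal genes. Gh stood at 1270, 233 and 121 CPM in 3 libraries and at 1.5 CPM or less in the others, and the striatal mean was 6.34 in the wild-type vehicle library of 10 h.

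The comparison at 10 h asked which transcripts change later in LepRb cells, as the mean of the effects in wild-type and ob/ob mice. The transcripts of 4 genes rose and none fell. Timp1 (ENSMUSG00000001131; chromosome X, 20870166 to 20874735) rose 9.53-fold (log2 3.25, SE 0.356, adjusted p = 0.00347). Stat3, the transcription factor activated by LepRb (ENSMUSG00000004040; chromosome 11, 100885098 to 100939540), rose 2.16-fold (log2 1.11, SE 0.13, adjusted p = 0.00388). Socs3 rose 4.88-fold (log2 2.29, SE 0.308, adjusted p = 0.0204). Irf9, a partner of STAT proteins in the interferon response (ENSMUSG00000002325; chromosome 14, 55603571 to 55610030), rose 2.51-fold (log2 1.33, SE 0.195, adjusted p = 0.0302). Timp1 lies within Syn1 on the other strand, Irf9 overlaps Rnf31 on the same strand and Stat3 overlaps Stat5a, so that some of their reads could belong to these neighbours.

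Of 22 JAK-STAT feedback genes 3 rose (Socs3, Stat3 and Irf9) and 6 rose adjusted over the list alone (camera adjusted p = 8.33e-08), and the call held with an estimated correlation (adjusted p = 0.0257). Of 13 measured acute phase genes 1 rose and 6 rose adjusted over the list alone, Timp1 and 5 Serpina3 paralogs (median 1.67, adjusted p = 4.56e-09), and this call also held (adjusted p = 0.0257 with an estimated correlation). Members of this list were in part chosen from knowledge of leptin-regulated genes, so its count is not independent evidence. Atf3 stood at 1.67 (SE 0.397, adjusted p = 0.258), Pomc at 0.73 (adjusted p = 0.395), Agrp at -0.15 (adjusted p = 0.955) and Npy at -0.02 (adjusted p = 0.995). Of 12 oligodendrocyte markers 7 fell adjusted over the list alone (median -0.81, adjusted p = 1.59e-11; adjusted p = 0.182 with an estimated correlation) and of 12 microglia markers 4 (median -1.04, adjusted p = 7.68e-08; adjusted p = 0.328 with an estimated correlation). The glial marker mean was 4.31 in the wild-type vehicle library and 3.5 in leptin beads of wild type, and 4.41 and 3.62 in those of ob/ob mice.

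In all 4 of 18212 genes passed at 10 h in beads, 1656 had an unadjusted p under 0.05, and DESeq2 called 108 and limma voom 2 (Timp1 and Stat3). With the 10 h libraries alone 75 genes passed, 16 higher and 59 lower, and Timp1 (2.93, adjusted p = 0.123) and Socs3 (2.14, adjusted p = 0.0758) did not. That fit had a term for genotype and a term for leptin in place of the mean of the genotype effects. With the glial index as a covariate Socs3 (1.97, adjusted p = 0.162) and Irf9 (1.09, adjusted p = 0.162) lost their calls. Library totals also took the call from Irf9 (1.29, adjusted p = 0.063). Irf9 lost its call without any 1 of the 3 wild-type leptin lysates (adjusted p = 0.0661 to 0.0821), Socs3 without ob/ob vehicle 2 (adjusted p = 0.0654), and 21 genes passed without ob/ob vehicle 1.

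Within wild-type mice at 10 h, 3 leptin libraries against 1 vehicle library, no gene passed by edgeR; 879 had an unadjusted p under 0.05, DESeq2 called 6 and limma voom 0. The values of the same genes were 1.92 (SE 0.463) for Timp1, 0.63 (SE 0.18) for Stat3 and 1.45 (SE 0.412) for Socs3, each with adjusted p = 0.902. Of 22 JAK-STAT feedback genes 2 rose adjusted over the list alone (list adjusted p = 2.09e-05; adjusted p = 0.126 with an estimated correlation). Of 12 oligodendrocyte markers 7 fell adjusted over the list alone (median -0.98; adjusted p = 0.22 with an estimated correlation). The 1 vehicle lysate was rich in striatal transcripts. In beads the median leptin effect of 20 striatal genes was -0.894 (-1.21 to -0.522, an interval over the genes and not over libraries), with 19 of 20 negative.

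Within ob/ob mice at 10 h, 1 leptin library against 2 vehicle libraries, the question was what leptin restores where it is absent. Timp1 rose 24.1-fold (log2 4.59, SE 0.496, adjusted p = 0.00241) and Stat3 3.01-fold (1.59, SE 0.178, adjusted p = 0.00241). Socs3 rose 8.69-fold (3.12, SE 0.436, adjusted p = 0.0181) and Irf9 3.72-fold (1.90, SE 0.271, adjusted p = 0.0181). Serpina3n, a serine protease inhibitor of the acute phase (ENSMUSG00000021091; chromosome 12, 104406729 to 104414329), rose 7.24-fold (2.86, SE 0.369, adjusted p = 0.0181), from 39.5 ± 4.39 CPM (n = 2) to 289 CPM in the leptin library. The JAK-STAT feedback list (3 of 22 rose, 4 adjusted over the list alone) and the acute phase list (2 of 13 rose, 6 adjusted over the list alone) passed with adjusted p = 0.0392 and 0.0291 with an estimated correlation. The leptin arm is 1 library, whose spread is assumed to be that of the other groups, so these values do not show a response beyond that library. Timp1 stood at 5.54 without vehicle 2 and at 4.05 without vehicle 1. The leptin library also had 121 CPM of Gh in the depleted fraction, and in beads the medians of astrocyte and microglia markers were -0.76 and -1.18, with adjusted p = 0.406 and 0.31 with an estimated correlation. By edgeR 5 genes passed and 718 had an unadjusted p under 0.05; DESeq2 called 23 and limma voom 3, without Socs3 (adjusted p = 0.817) and Irf9 (adjusted p = 0.14). Irf9, Serpina3n and Socs3 lost their calls when either vehicle library was left out, without vehicle 1 each with adjusted p = 0.116 and without vehicle 2 with adjusted p = 0.0853, 0.26 and 0.479. In these fits 12 genes passed without vehicle 1 and 2 without vehicle 2.

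No gene passed by edgeR for a difference of the leptin effects between the genotypes at 10 h, with 251 of 18212 genes at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma voom. With 1 library in 2 of the arms, this test called 4.48% of 2-fold and 57.6% of 4-fold changes in simulated data, so the absence of calls does not show equal effects. The difference, ob/ob minus wild type, was 2.67 (SE 0.655) for Timp1, 2.37 (SE 0.5) for Serpina3n, 1.67 (SE 0.579) for Socs3 and 0.95 (SE 0.249) for Stat3, each with adjusted p = 1. Of 13 acute phase genes 4 passed adjusted over the list alone (list adjusted p = 0.00161; adjusted p = 0.375 with an estimated correlation).

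In the depleted fraction at 10 h, which asked for the later response in the RNA left after the pull-down, 1 of 19115 genes passed. Strip2, a gene also expressed in striatum (ENSMUSG00000039629; chromosome 6, 29917012 to 29959681), fell by 0.749 on the log2 scale (SE 0.0743, 0.595-fold, adjusted p = 0.000937). Its level was 68 CPM in the 1 wild-type vehicle library and 29.9 ± 1.72 CPM in the 3 wild-type leptin libraries, against 28.6 ± 0.859 CPM in the 4 vehicle libraries of 3 h. That library had the highest value of all 14 depleted libraries for each of 20 striatal genes, and in ob/ob mice alone Strip2 stood at -0.29 (adjusted p = 1) and no gene passed. Of 23 feeding neuropeptides 5 fell adjusted over the list alone, with Tac1 at -0.51 (adjusted p = 0.114) and Pdyn at -0.65 (adjusted p = 0.143); the list had adjusted p = 0.0123, and adjusted p = 0.718 with an estimated correlation. By edgeR 1717 genes had an unadjusted p under 0.05; DESeq2 called 116 and limma voom 1. Without wild-type leptin 2, 16 genes passed, and without ob/ob vehicle 1, 9 did.

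The response shared by the 3 strata, 7 leptin against 7 vehicle libraries, gave 4 genes in beads. Socs3 rose 4.4-fold (log2 2.14, SE 0.228, adjusted p = 0.0024), Atf3 4.15-fold (2.05, SE 0.263, adjusted p = 0.0105) and Arid5a 2.77-fold (1.47, SE 0.226, adjusted p = 0.0454). Gpr6, an orphan receptor gene that is also on the list of striatal genes (ENSMUSG00000046922; chromosome 10, 41069977 to 41072285), fell to 0.49-fold (log2 -1.03, SE 0.144, adjusted p = 0.0105) and stood at -1.22 (SE 0.2) at 3 h. Of 22 JAK-STAT feedback genes 1 rose and 10 rose adjusted over the list alone (adjusted p = 2.81e-09), and the call held with an estimated correlation (adjusted p = 0.00386). Of 25 ER stress genes 1 rose, Atf3; adjusted over the list alone 2 rose (Atf3 and Asns) and 9 fell, chaperones such as Hspa5, Calr and Hsp90b1 (adjusted p = 0.00781; adjusted p = 0.27 with an estimated correlation).

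Glial markers had lower values in leptin beads in the shared comparison as well. Adjusted over the list alone, 9 of 12 astrocyte markers (median -0.69, adjusted p = 3.6e-08; adjusted p = 0.184 with an estimated correlation) fell. So did 7 of 12 oligodendrocyte markers (median -0.50, adjusted p = 4.12e-09; adjusted p = 0.183 with an estimated correlation) and 8 of 12 microglia markers (median -0.78, adjusted p = 4.21e-09; adjusted p = 0.183 with an estimated correlation). With the glial index as a covariate no gene passed (Socs3 1.91, adjusted p = 0.203; Atf3 2.28, adjusted p = 0.15). Without the 3 lysates richest in pituitary transcripts 273 genes passed, 58 higher and 215 lower. Of the lower genes 198 had lower estimates in beads than in the depleted fraction, and of the higher ones 55 had higher estimates, with no threshold applied. The lysates left out include the 2 that made the arms of 3 h overlap in glial content. By edgeR 4 of 18212 genes passed and 2012 had an unadjusted p under 0.05; DESeq2 called 140 and limma voom 5. Leaving out vehicle m3 gave 82 genes, leptin f2 48 and leptin m24 2, without Gpr6 (adjusted p = 0.0644) and Arid5a (adjusted p = 0.122). Arid5a lost its call in 9 of 14 such fits (adjusted p = 0.0571 to 0.122). Over all alternatives it lost its call in 11 of 23, library totals among them.

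**Figure D4:**
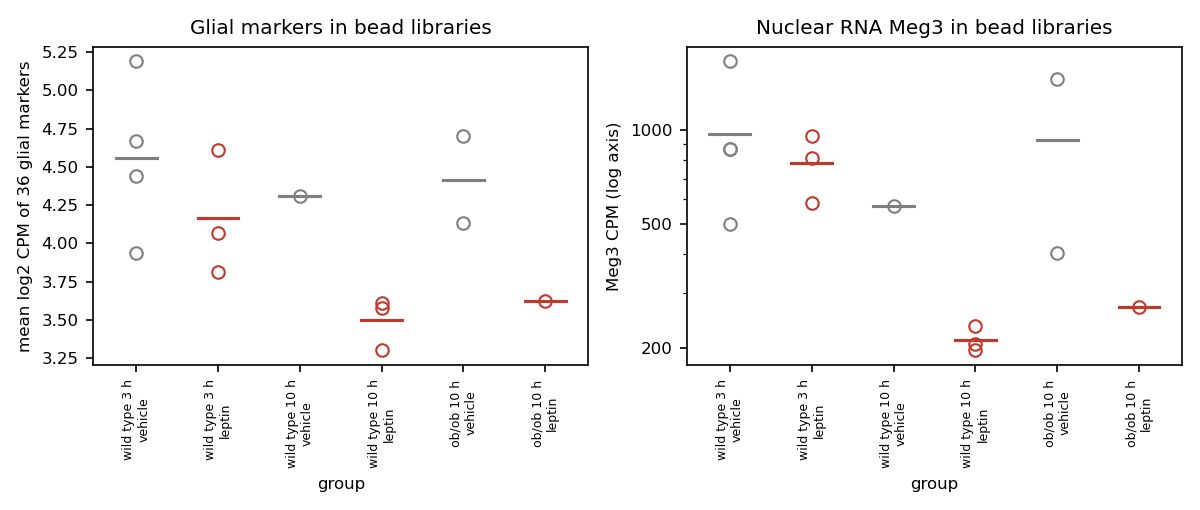
Mean log2 CPM of 36 glial markers, and CPM on a log axis of the nuclear RNA Meg3, in the 14 bead libraries by group (points are libraries, lines are group means; grey vehicle, red leptin). The glial mean was 4.56 in vehicle and 4.16 in leptin beads at 3 h, 4.31 and 3.5 in wild type at 10 h, and 4.41 and 3.62 in ob/ob mice.

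The shared leptin effect was larger in beads than in the depleted fraction for 6 of 19682 genes: Atf3 (difference 1.48, SE 0.236), Socs3 (1.33, SE 0.201), Gcnt2 (0.98, SE 0.156), the growth arrest gene Gadd45g (0.90, SE 0.148), Etv6 (0.82, SE 0.137) and Sbno2 (0.62, SE 0.103), each with adjusted p = 0.0357. JAK-STAT feedback genes as a list had a larger effect in beads (1 of 22 passed, 7 adjusted over the list alone, median 0.21) and held with an estimated correlation (adjusted p = 0.00201). Erythrocyte genes had a more negative one (2 of 5 adjusted over the list alone, median -0.54), which also held (adjusted p = 0.0453). Other transcripts depleted in beads went the same way, with medians over all strata of -0.672 in beads and -0.239 in the depleted fraction for glial markers and -0.708 and -0.0417 for nuclear RNAs. The edgeR test gave 1052 genes with an unadjusted p under 0.05 (984 expected with no true difference), DESeq2 called 22 and limma voom 7. No gene passed with library totals, with the filter of 1 CPM in 7 libraries, without the robust option, or without the lysate block. None passed either without any 1 of vehicle m1, m3 or f3, leptin m24 or f4, wild-type leptin 1 of 10 h, ob/ob vehicle 1 or ob/ob leptin 1. In turn 21 passed without leptin f2, 2 without wild-type vehicle 1 of 10 h and 1 without ob/ob vehicle 2.

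Whether early changes were seen again later was tested in the 10 h bead libraries, which are independent of those of 3 h but share the estimate of spread. All 4 genes that passed at 3 h had the same sign at 10 h, in the mean of the genotypes (0.42 to 2.29), in wild type alone (0.25 to 2.18) and in ob/ob mice alone (0.59 to 3.12). As a set they were higher at 10 h (camera with an estimated correlation, adjusted p = 0.0214). Of these genes Socs3 also passed at 10 h. No gene differed between the 10 h and 3 h effects by edgeR, with 957 of 18212 genes at an unadjusted p under 0.05, 6 called by DESeq2 and 0 by limma voom. The difference, 10 h minus 3 h, was 2.43 (SE 0.447) for Timp1, 1.70 (SE 0.358) for Serpina3n, 0.89 (SE 0.256) for Irf9, 0.68 (SE 0.172) for Stat3 and -0.59 (SE 0.506) for Atf3, with adjusted p of 0.792 for the first 4 and 0.809 for Atf3. Of 13 acute phase genes 3 passed adjusted over the list alone (list adjusted p = 3.21e-05; adjusted p = 0.15 with an estimated correlation). Of the 4 genes called at 3 h, Socs3 and Atf3 were enriched in beads in the 10 h lysates alone, 50% against 37.9% of the other genes tested (Fisher's exact test, two-sided, p = 0.637). Leptin was given to 4 of these 7 lysates, and over all strata the estimated leptin effect on both genes was larger in beads. Their enrichment there can therefore restate part of the leptin effect. The difference between fractions at 10 h alone was not tested. At a fold of at least 2 the shares were 50% and 4.75% (Fisher's exact test, two-sided, p = 0.0127).

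The comparison of ob/ob with wild-type mice at 10 h, as the mean of the vehicle and leptin arms, asked how bead RNA differs between the genotypes. Since the leptin arm had received leptin, it is not a test of the lack of leptin alone. Lep itself gave 4 counts over all libraries, so it checks nothing here. Pomc was 7.24-fold lower in ob/ob beads (log2 -2.86, SE 0.234, adjusted p = 0.000127), at 83.4 ± 30.4 CPM (n = 2) in vehicle beads against 743 CPM in the 1 wild-type vehicle library. Nts, the neurotensin gene (log2 -1.70, SE 0.216, adjusted p = 0.00417), Cartpt (-1.78, SE 0.336, adjusted p = 0.047) and Pdyn, the prodynorphin gene (-0.70, SE 0.129, adjusted p = 0.0296), were lower too. The receptor genes Glp1r (-0.95, SE 0.152, adjusted p = 0.0111) and Npy2r (-1.25, SE 0.212, adjusted p = 0.0158) followed. The 1 wild-type vehicle lysate was the one rich in striatal transcripts, and in leptin libraries alone Pdyn stood at -0.58 (adjusted p = 0.522). Agrp (2.06, SE 0.57, adjusted p = 0.241) and Npy (1.65, SE 0.466, adjusted p = 0.235) did not pass.

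Of 24 LepRb neuron markers 5 fell over all genes (with the adjustment over the list alone 15 fell and 3 rose; adjusted p = 8.22e-12, adjusted p = 0.174 with an estimated correlation). Of 15 glucocorticoid and fasting genes 4 rose and 11 rose adjusted over the list alone (median 0.90, adjusted p = 8.22e-12; adjusted p = 0.0754 with an estimated correlation). These included the cell cycle inhibitor gene Cdkn1a (log2 1.58, SE 0.199, adjusted p = 0.00388), the metallothionein genes Mt1 (1.03) and Mt2 (1.52), and Fkbp5, a target of the glucocorticoid receptor (0.89, SE 0.137, adjusted p = 0.00893). Cdkn1a (1.63), Mt1 (0.531), Mt2 (0.535) and Fkbp5 (0.993) also rose in the depleted fraction. Erythrocyte genes rose in 2 of 5 cases, Hbb-bs (1.38) and Hba-a1 (1.43), and this list held with an estimated correlation (adjusted p = 0.0123); reads can be shared between the globin paralogs. These genes are depleted in beads (median -1.62), and the bead library of ob/ob vehicle 2 had 0.505% mitochondrial counts against at most 0.108% in the other 13, so RNA carried over into beads can add to their values. Hbb-bs (1.1) and Hba-a1 (1.16) also rose in the depleted fraction, so their rise was not limited to beads. Stat3 (-0.63, adjusted p = 0.0434), Serpina3n (-1.40, adjusted p = 0.0428) and the interferon gene Ifi27 (-0.95, adjusted p = 0.00388) were lower, and Socs3 stood at -1.38 (adjusted p = 0.0716). The chemokine gene Ccl17 (2.18), Alkal2 (1.88), Itgad (2.35), Lyve1 (2.57), Rhoj (1.21) and 1700016P03Rik (2.07) rose. Among the lowest were pseudogenes and unnamed genes such as Gm15459 (-5.76), Gm45104 (-5.28) and Atp6v0c-ps2 (-4.69), whose reads are uncertain. These 3 genes were lower in the depleted fraction too (-5.55, -3.74 and -4.47). Pseudogenes made up 10.5% of the genes past the threshold in beads, against 4.56% of genes tested, and the cause was not tested.

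In all 86 of 18212 genes passed, 23 higher and 63 lower in ob/ob mice, and 1782 had an unadjusted p under 0.05. DESeq2 called 228 and limma voom 62. In the depleted fraction 1064 of 19115 genes passed in the same contrast, so the difference was not limited to beads. Of 31 named genes that passed between the genotypes in beads, 1 kept its call under every alternative. Genotype and sequencing run cannot be told apart. In leptin libraries alone 3 genes passed, Pomc (-2.56, adjusted p = 0.0295) and Mt2 (1.54, adjusted p = 0.0401) among them, and in vehicle libraries alone 14; 40 passed without ob/ob vehicle 2 and 44 without wild-type leptin 2.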

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

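The tests of carry-over, of each glial cell type, of pituitary hormones raised by leptin, of striatal tissue, of striatal transcripts lowered by leptin, of the segment around Lep and of the 21 genes lower in beads were chosen after the results had been seen, as were the fits without the lysates richest in pituitary transcripts; the other tests of this part were chosen before.

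In 5 of 38 tests of a group of 4 libraries, 1 library lay far from the others. The tests come from 2 groups, the bead and depleted libraries of the same 4 lysates, so they are not independent. Their number is therefore not set against a chance rate. Among wild-type vehicle libraries of 3 h, Agrp in beads was 292 CPM in m3 against 62.9 to 89.5 CPM, Serpina3n in beads 321 CPM in m3 against 166 to 173 CPM, and Agrp in the depleted fraction 4.9 CPM in m3 against 2.79 to 2.92 CPM. Cartpt in the depleted fraction was 100 CPM in f1 against 53.3 to 55.2 CPM, and Npy 18.9 CPM in m1 against 22.1 to 22.2 CPM.

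The leptin effect differed between the fractions for a few genes by a test of the difference itself, but these calls were not stable. Over all strata no gene passed with library totals or without the lysate block. At 3 h no gene passed without leptin m24. Other splits did not exclude chance for either difference. In the main fits the leptin effect at 3 h was larger in beads for Arid5a (1.84) and Etv6 (1.14). Over all strata it was larger in beads for Atf3 (1.48), Socs3 (1.33), Gcnt2 (0.98), Gadd45g (0.90), Etv6 (0.82) and Sbno2 (0.62), and the list medians of the difference were 0.205 for JAK-STAT feedback and -0.543 for erythrocyte genes.

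The 36 glial markers had lower values in leptin beads (median over all strata -0.672, interval -0.731 to -0.498). Intervals of medians in this part come from resampling the genes, so they leave out the spread between libraries. A fall of glial transcripts in the tissue would show in the depleted fraction too, where the median was -0.239 (-0.415 to -0.0898). That fall is smaller than the one in beads, as are those of astrocytes (-0.253) and oligodendrocytes (-0.0389). Without the spread between libraries, these values do not decide whether such a fall is the whole cause. For microglia the median in the depleted fraction was -0.497 (-0.553 to -0.385) against -0.778 in beads, which leaves it open as well. Nuclear RNAs lower in beads were also lower in leptin beads (median -0.708, 8 of 8 negative, against -0.0417 in the depleted fraction). Less unbound RNA carried over into the leptin bead libraries is therefore a candidate explanation for transcripts depleted in beads. Endothelial and mural markers were also lower in leptin beads at 3 h, although that list did not pass as lower in beads. Carry-over alone would not account for them. The mitochondrial share of bead counts was lower with leptin at 10 h (0.0177% to 0.0254% against 0.108% in wild type, 0.012% against 0.0872% and 0.505% in ob/ob mice), but at 3 h the arms overlapped (0.024% to 0.0447% against 0.0238% to 0.0677%).

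Transcripts of neighbouring tissues were high in single lysates. The Pomc effect at 3 h in the depleted fraction was 2.10 (SE 1.03) with all lysates and -0.257 (SE 0.252) without vehicle m3 and leptin f2, so pituitary tissue in these lysates is a candidate explanation. Gh was higher in every leptin library than in every vehicle library in 1 of 3 strata, and vehicle m3 had 233 CPM against 1.12 CPM or less in 2 leptin libraries of 3 h, which argues against leptin raising pituitary hormone transcripts in all groups. For striatal tissue in the wild-type vehicle lysate of 10 h, 20 of 20 striatal genes were higher in its depleted library than in all 13 others (by 0.156 to 1.99 on the log2 scale). Leptin lowering striatal transcripts in all groups stays open: the striatal mean was lower in every leptin library in 1 of 3 strata, while the median effect was -0.295 at 3 h (-0.4 to -0.065), -0.335 in ob/ob mice and -1.23 in wild type at 10 h.

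Of the 86 genes past the threshold between ob/ob and wild-type beads, 59 had the same sign and an unadjusted p under 0.05 in the depleted fraction (68.6%). That share was not counted over all genes, and 1064 of 19115 genes passed in the depleted fraction as a whole. LepRb transcripts left in that fraction can add to the count of 59. However, 21 of the 59 genes had lower estimates in beads than in the depleted fraction, with a median ratio of the depleted to the bead effect of 0.655. These genes were picked by their effect in the depleted fraction, which favours a large ratio. The ratio therefore does not decide whether the change was in LepRb cells alone. A linked segment around Lep stays open: 3 of the 86 genes lie within 20 Mb of it (3.49% against 1.16% of genes tested; Fisher's exact test, two-sided, p = 0.079), and 9 lie on chromosome 6 as a whole (10.5% against 5.01%; Fisher's exact test, two-sided, p = 0.04). A difference between sequencing runs cannot be told apart from genotype, since 0 runs hold both genotypes at 10 h.

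Other splits of the same libraries were counted for the comparisons with at least 3 libraries per arm, taken over genotypes. For bead against depleted RNA 1 of 100 splits gave as many genes, the real one (15333, highest other 7806), so chance is excluded. For the shared leptin effect in beads 4 of 100 splits gave as many as the real 4 genes (highest other 1227), a share under 0.05. These 100 are a sample of 420 possible splits, so a share this close to 0.05 is not established over all of them. Chance is not excluded for 3 h in beads (5 of 35 splits; real 4, highest other 940) and 3 h beads minus depleted (3 of 35; real 2, highest other 2376). The same holds for the shared difference between fractions (4 of 60; real 6, highest other 999). For 3 h in the depleted fraction (35 of 35; real 0, highest other 12) and 10 h minus 3 h (100 of 100; real 0, highest other 805) the real count of 0 fixes the outcome, so these counts say nothing about chance. For 10 h in beads (real 4, highest other 426; as many in 2 of 12), 10 h in the depleted fraction (real 1, highest other 3; 6 of 12) and ob/ob against wild type (real 86, highest other 2; 1 of 12) the splits are too few for a share under 0.05.

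Splits that called many genes point to a structure of the samples. At 3 h the split with 940 genes in beads set leptin f4, leptin m24 and vehicle m3 apart from the rest; their glial means were 3.81 to 4.07 against 4.44 to 5.19 in the other 4 bead libraries. At 10 h the split with 426 genes put ob/ob vehicle 2 with wild-type vehicle 1 and wild-type leptin 1 and 2.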

How the results depend on the processing

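Fits without the lysates richest in pituitary transcripts, the ob/ob libraries alone in the depleted fraction and the use of 50 genes at 10 h were chosen after the data had been seen. The genotype difference in leptin or vehicle libraries alone was also chosen then. No named gene that passed turned its direction under any alternative run. Counts of genes past the threshold that moved by more than 1.5 times are given here in the order bead against depleted, 3 h bead, 3 h depleted, 3 h difference between fractions, 10 h bead, 10 h wild type, 10 h ob/ob, 10 h depleted, all bead, all difference between fractions, 10 h minus 3 h, ob/ob minus wild type, and ob/ob against wild type; unless a reason is named, the cause was not tested.

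With DESeq2, from the second on, the counts were 22, 62, 7, 108, 6, 23, 116, 140, 22, 6, 1 and 228, and without a filter 191, 640, 24, 465, 184, 136, 592, 613, 245, 108, 35 and 394. A fold of at least 2 left 3473 genes between fractions, by construction. With limma voom 10 h bead gave 2 and 10 h ob/ob 3, with RLE size factors all bead gave 20, and without the robust option 10 h bead gave 12. With the glial index as a covariate 3 h bead gave 2, without Socs3 (1.96) and Atf3 (2.38), and all bead 0; 10 h bead lost Socs3 (1.97) and Irf9 (1.09). Parts of the libraries gave 75 for 10 h bead (10 h alone), 0 for 10 h depleted (ob/ob alone), and 3 (leptin alone) and 14 (vehicle alone) for ob/ob against wild type; all of these use fewer samples, which does not account for the rise at 10 h. The fit of the 10 h bead libraries alone also had a different model, with a term for genotype and a term for leptin. Without the pituitary-rich lysates the counts were 34 (3 h bead), 1 (3 h depleted), 79 (3 h difference), 273 (all bead) and 11 (all difference). The all difference gave 0 by edgeR with library totals, with the filter of 1 CPM in 7 libraries and without the robust option. As reported, DESeq2 called 22 and limma voom 7. By edgeR 1052 genes had an unadjusted p under 0.05, against 984 expected with no true difference.

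Without the lysate block, which ignores the pairing, bead against depleted gave 15126 genes, the 3 h difference 2 and the all difference 0.

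With 1 lysate left out the lowest and highest counts were 14965 and 15456, 3 and 17, 0 and 14, 0 and 8, 3 and 21, 0 and 0, 2 and 12, 1 and 16, 2 and 82, 0 and 21, 0 and 0, 0 and 0, and 40 and 62, in the order given. A lone library left in an arm is assumed to vary like the other groups. Fits without the lone wild-type vehicle or ob/ob leptin lysate were not run for the 10 h comparisons, since no arm would be left.

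Gene lists past the threshold went from 10 to 0, 15 to 0, 14 to 0, 3 to 0, 13 to 2, 10 to 0, 10 to 2, 7 to 0, 16 to 1, 14 to 2, 5 to 0, 6 to 0 and 12 to 1 with an estimated correlation. With the 50 genes of smallest p at 3 h, 44 had the same sign at 10 h, against 4 of 4.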

Other observations

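The test of the 50 genes below was chosen after the result had been seen.

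Families of transcripts differed between the fractions. All 17 transcripts encoded in mitochondria were lower in beads (median -4.31; -4.49 with library totals and -4.35 with RLE size factors), and they took 0.012% to 0.505% of bead counts against 0.807% to 1.31% of depleted counts. Of 77 ribosomal protein genes 69 were higher in beads and 2 lower (median 0.93; 0.76 with library totals). Of 909 lincRNA genes 160 were higher and 470 lower (median -0.45).

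The nuclear RNA Xist was higher in beads than in the depleted fraction in 3 h lysates with the letter f, by 2.65 to 4.13 on the log2 scale, and stood at -1.04 to 2.02 in the lysates of 10 h.

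A response to leptin shared by 3 h and 10 h was tested with the 50 genes of smallest p at 3 h in beads. Of these 44 had the same sign at 10 h (88%, interval 75.7% to 95.5%), against 53.9% of all genes. The interval treats the genes as independent, which genes measured in the same libraries are not. Of 31 higher at 3 h 27 were higher at 10 h, and of 19 lower 17 were lower. Tested as sets at 10 h, the higher genes had adjusted p = 0.0488 and the lower ones adjusted p = 0.0738 (camera with an estimated correlation). With the 10 h libraries split in other ways the highest number was 37. Only 1 of 12 splits, the real one, gave 44, but 12 splits are too few for a share under 0.05. The signs go with a shared response but do not establish it. Glial content, which was lower in leptin beads at both times, was not removed in this test.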
